A study of Homo sapiens with 8 samples.

How the data were processed

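Circular RNA was measured in subcutaneous tumors of the human liver cancer cell line HepG2 grown in immunodeficient nude mice. The series holds 8 one-colour arrays, 4 labelled as untreated control and 4 labelled as treated by incomplete ultrasound-guided radiofrequency ablation (RFA). Groups and replicate numbers were taken from the sample descriptions and titles. The labels describe 8 mice, 4 per group, but do not tie an array to an animal, so the p-values measure the spread between these arrays.

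Per the labels' protocols, total RNA was digested with RNase R, an exonuclease that removes linear RNA, and was then labelled with Cy3 from random primers. Per the file headers, the arrays were read on an Agilent scanner with Feature Extraction 11.0.1.1, and the headers name the genome build hg19. The deposited processed signal is a linear intensity from which Feature Extraction had subtracted background and removed spatial trends within the array, per the file headers, with no scaling between arrays. The deposited median signal and local background are raw intensity values. The authors also deposited a value table of the same arrays, whose values are on the log2 scale. The submitters' processing notes name limma without a version or a role. How that table was scaled between arrays is not given in the sources used here. Each of its columns correlated with the log2 median signal of the same array at 0.997 to 0.999 across probes, so it carried no background subtraction and no centring of probes. Its column medians were 5.20, 5.18, 5.20 and 5.19 for control replicates 1 to 4 and 5.18, 5.19, 5.22 and 5.19 for RFA replicates 1 to 4.

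Each array carried 13617 circRNA probes with 1 spot each and 70 mRNA probes with 10 spots each. It also carried 60 negative probes and 15 circRNA control probes, which were left out of the tests. The files do not pair the circRNA probes with circRNA names, classes or host genes. The 15 host gene lists, the 23 circRNAs known from liver cancer or other studies and the counts by circRNA class, all fixed before the data were examined, were therefore not tested on circRNAs. The mRNA probes carry transcript accessions, and all 70 matched a gene symbol in a RefSeq table of assembly GRCh38.p14, used for names only. Testing these mRNA probes, and grouping them by the fixed lists, was decided after the files were seen. The mRNA signal was taken to come from linear RNA left after the digestion, which was not tested. Other RNA that resisted the digestion was not told apart from it. The level of an mRNA is relative to the circRNA probes of the same array.

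The log2 processed signal, with signals under 1 set to 1, was reduced by the 75th percentile of all circRNA probes of the array. That floor applied to 0 of the tested circRNA values. Spots with a non-uniformity or population outlier mark were left out, and no circRNA spot was saturated. A circRNA was tested where it was well above background on at least 4 of the 8 arrays, which held for 8696 circRNAs. A further 5 were left out because a group kept fewer than 2 unmarked values, so 8691 were tested. An mRNA probe was tested where at least 50% of its spots were well above background on at least 4 arrays, which held for 47, and its spots were averaged on the log2 scale.

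Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the circRNAs and, in a separate fit, over the mRNAs, and a threshold of adjusted p under 0.05. Members of a fixed list were also adjusted over the list alone, with no correction across the lists. No list had the 5 tested members that the set tests required, so no set test was run. Signal and detection per array were compared by exact permutation over the 70 assignments of the arrays, for which the smallest two-sided p is 0.0286. Array similarity was compared over the 35 splits of the arrays. Correlations across arrays were tested by exact permutation (two-sided), over all orders of the 8 arrays and, for values centred within groups, over the 576 orders within groups, in Python 3.11.15 with numpy 2.4.6. Figures were drawn with matplotlib 3.10.9.

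The circRNAs to be named were, where none passed the threshold, the 10 per direction with the smallest p whose groups did not overlap. The 12 mRNAs with the smallest p and every tested member of a fixed list were named by a rule set after the files were seen. ACTG1, ZZZ3 and GAPDH were added after their values were seen. Where no name is paired with a probe, 2 identifiers per direction are printed and the rest are summarised.

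The fit was tested on simulated arrays drawn from the means and spreads of the 8691 circRNAs, with 200 of them changed. It recovered 0% of those changed 2-fold, 90.5% of those changed 4-fold and 97.0% of those changed 8-fold. With the same shifts added to the real arrays, it recovered 0%, 81.0% and 93.0%. It also called 1, 14 and 12 unchanged circRNAs on the simulated arrays, and 0, 1 and 1 on the real arrays. These shares hold for 200 circRNAs changed together, and fewer were not simulated. Recovery after adjustment depends on that number, so a count of 0 would not exclude that a few circRNAs changed 4-fold or more. The number of arrays limits the precision.

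Alternatives fixed beforehand were quantile and median scaling, another probe set for the percentile, normexp background correction with an offset of 50, no filter or a stricter filter, the replicate number as a block, array weights, an intensity trend in the variance, the deposited log2 table, other thresholds and the omission of each array. Normexp was planned on the mean signal, which was not used here, and was run on the median signal. Its offset shrinks the log2 folds of weak probes, so a smaller fold with normexp is not by itself evidence against a change. Added after the data were seen were cyclic loess and fits with array brightness or the first principal component as a covariate. All 8 arrays shared 1 scan, so slide and scan could not enter the fit. On the slide, the control arrays lay in 1 row and the RFA arrays in another, so row and group cannot be told apart. In both rows the replicate number was the array's column.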

Results

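Incomplete RFA heats a tumor through a needle electrode and leaves part of it viable. The series asks how circRNAs, closed RNA loops made by back-splicing, differ between HepG2 tumors so treated and untreated tumors. The data comprise 4 arrays of incompletely ablated tumors and 4 of untreated tumors. The 75th percentile of the processed signal ranged from 44.7 to 67.1 between arrays, with a mean of 52.5 ± 9.98 (SD, n = 4) in control and 51.4 ± 7.79 (SD, n = 4) in RFA tumors. Between 7679 and 9589 of the 13617 circRNA probes were well above background, 56.4% to 70.4% of them. The mean was 8468 ± 517 (SD, n = 4) in control and 8573 ± 819 (SD, n = 4) in RFA tumors. Neither the percentile on the log2 scale (exact permutation, two-sided p = 0.80) nor the number of detected circRNAs (exact permutation, two-sided p = 0.857) separated the groups. Both differences changed sign without control replicate 3, to 0.10 on the log2 scale and -61.75 probes, or without RFA replicate 2, and the percentile also without RFA replicate 3. Among spots of the negative probes, which have no target, 12.3% to 20.7% per array were also marked well above background.

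The comparison of ablated with untreated tumors found no circRNA past the threshold. The circRNA probe ASCRP3011615 had the smallest p among the 8691 tested, with a log2 level of 0.54 ± 1.18 (SD, n = 4) in control and -1.96 ± 0.38 (SD, n = 4) in RFA tumors. Its log2 fold was -2.50 ± 0.52 (SE), with a limma adjusted p of 0.939. A second probe, ASCRP3001066, was at 2.47 ± 1.35 (SD, n = 4) in control and -0.64 ± 1.09 (SD, n = 4) in RFA tumors, a log2 fold of -3.11 ± 0.71 (SE) and an adjusted p of 0.939. In the other direction, ASCRP3002533 was at -2.18 ± 0.08 (SD, n = 4) in control and -1.29 ± 0.28 (SD, n = 4) in RFA tumors, a log2 fold of 0.90 ± 0.22 (SE). ASCRP3002644 was at -3.09 ± 0.20 (SD, n = 4) and -1.94 ± 0.52 (SD, n = 4), a log2 fold of 1.16 ± 0.29 (SE), and both had an adjusted p of 0.939. It was well above background on only 1 of 4 control and 3 of 4 RFA arrays. With normexp the 4 log2 folds shrank to -1.0, -1.88, 0.19 and 0.21, in the order given, and in the deposited log2 table to -1.59, -2.50, 0.34 and 0.41. In each of these 4 circRNAs, all 4 RFA values lay beyond all 4 control values, which the rule for naming them required. None of the 4 differences passed the threshold. The files do not pair these probes with circRNA names or host genes.

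**Figure D1:**
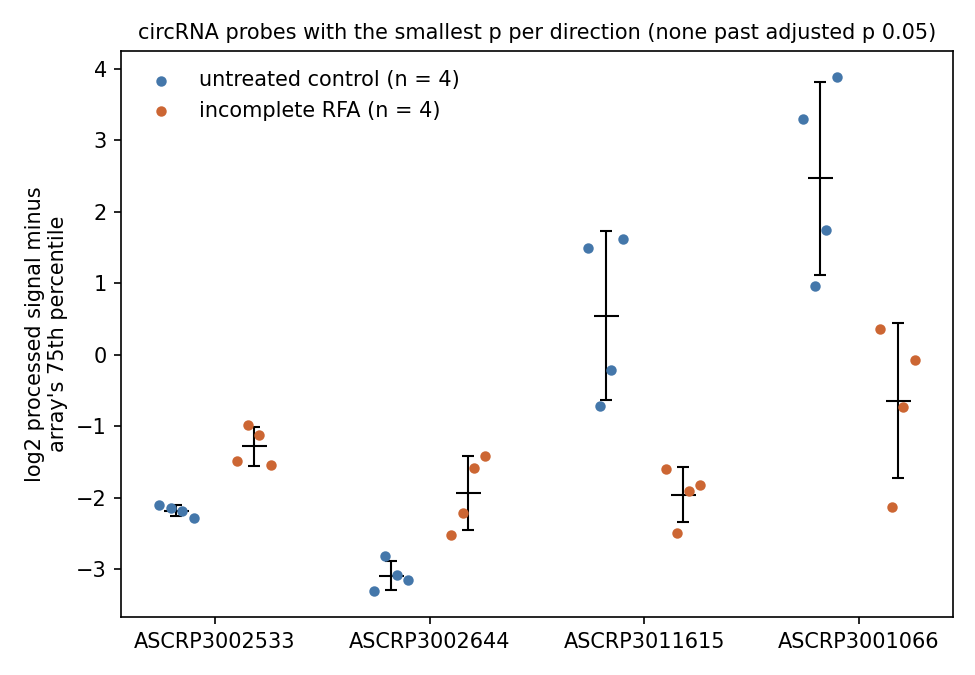
Log2 processed signal minus the array's 75th percentile (y axis) of 4 circRNA probes (x axis), with 1 point per array, the group mean as a horizontal mark and the SD as a bar, for 4 control and 4 RFA arrays. The groups do not overlap in any of the 4 probes, as the rule for naming them required, and each has a limma adjusted p of 0.939.

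Including those 4, 10 circRNAs were named per direction. The 10 named as higher in RFA tumors had log2 folds from 0.79 to 2.31 and unadjusted limma p from 0.00224 to 0.00544. The 10 named as lower had log2 folds from -3.11 to -0.77 and unadjusted p from 0.000860 to 0.00855. Every one of the 20 had an adjusted p of 0.939. Of the 10 named as higher, 5 were not well above background on every array, and 4 of these, among them the one at 0.79, were so on at most 2 of 4 control arrays. The 5 above background on all arrays had log2 folds from 0.90 to 1.07. Of the 10 named as lower, 2 were not well above background on every array. Groups that did not overlap were seen in 162 circRNAs higher and 50 lower in RFA tumors, 212 in all, where chance gives 124 per direction and 247 in all of the 8658 circRNAs measured on all arrays. The balance depended on the scaling, with 116 higher and 66 lower for median scaling, 122 and 80 for cyclic loess and 241 and 36 for the percentile over probes detected on all arrays, and with normexp it was 83 and 33.

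With limma, 0 of the 8691 circRNAs passed adjusted p under 0.05, 0 higher and 0 lower, and the smallest adjusted p was 0.939. At an unadjusted p under 0.05 there were 418 circRNAs, 262 higher and 156 lower, where 435 are given by chance. This balance depended on the scaling, with 195 higher and 195 lower for median scaling, 187 and 201 for cyclic loess, 260 and 96 for normexp with quantile normalization and 441 and 110 for the percentile over probes detected on all arrays, and with the replicate block it was 227 and 258. Leaving out 1 array gave from 164 to 741. The 95% confidence interval of the log2 fold had a median half-width of 0.70. For 4663 circRNAs, 53.7% of those tested, the interval excluded a change of 2-fold or more in either direction, and for the others a change of that size was not excluded. With normexp, whose offset shrinks the folds of weak probes, 7713 intervals lay within 2-fold. On that shrunken scale they do not exclude a change of 2-fold or more in level. At an unadjusted p under 0.05 with a fold of at least 1.5, without correction for the number of tests, 214 circRNAs were higher and 147 lower. These became 167 and 184 with median scaling, 188 and 177 with quantile normalization, 133 and 173 with cyclic loess, 14 and 35 with normexp, 220 and 258 with the replicate block and 364 and 103 with the percentile over probes detected on all arrays. With 1 array left out, the 361 in all ranged from 163 (98 higher, 65 lower) without RFA replicate 3 to 711 (433 higher, 278 lower) without control replicate 3.

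**Figure D2:**
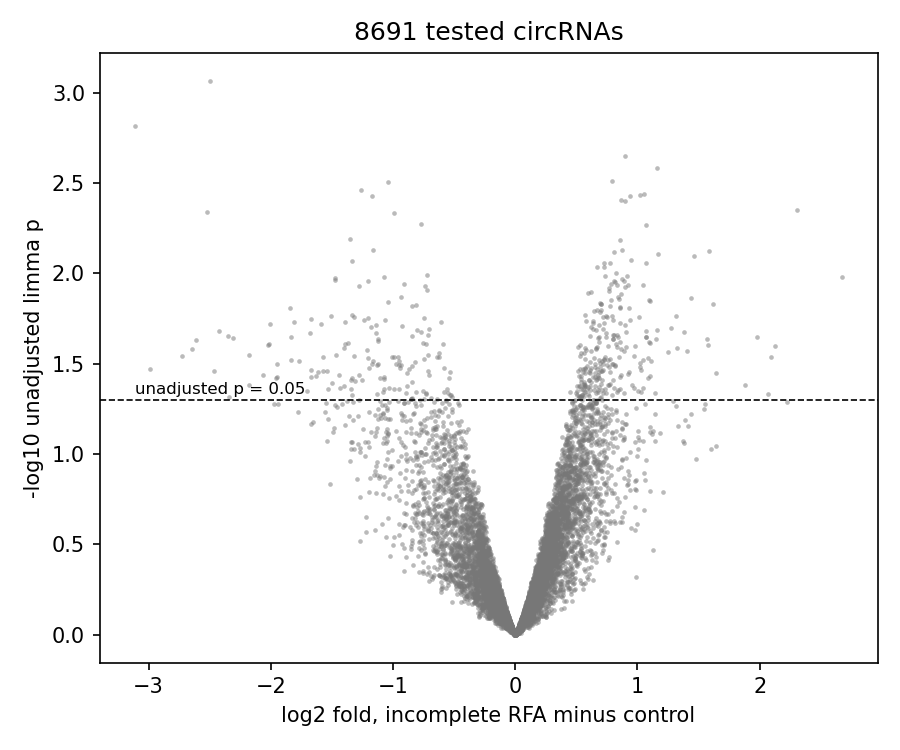
Log2 fold of RFA minus control (x axis) against -log10 of the unadjusted limma p (y axis), with 1 point for each of the 8691 tested circRNAs and a dashed line at the unadjusted 0.05 level. Above the line lie 418 circRNAs, 262 of them with a positive fold, and none of the 8691 passed adjusted p under 0.05.

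Detection in 1 group alone was seen in 4 of the 13617 circRNA probes, and 22 of the 35 splits of the arrays gave as many. The other splits had a median of 5.5 and a highest count of 76, so this count does not set the groups apart. A single circRNA was well above background on all 4 RFA arrays and on no control array, with a bound of 1.67-fold higher in RFA tumors. Another 3 were well above background on all 4 control arrays and on no RFA array, with bounds of 1.60-fold, 1.27-fold and 2.21-fold higher in control tumors. These bounds set the mean of the brighter group against the lowest signal called above background on each array of the other. They carry no sampling error, and spots of negative probes were also marked well above background, so they do not establish a minimum fold. Each of the 4 had a limma adjusted p of 0.939.

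The arrays were not detectably more alike within groups than between them. The mean Pearson correlation of log2 levels across circRNAs was 0.902 among control arrays, 0.953 among RFA arrays and 0.926 between groups. The mean within groups exceeded that between groups by 0.00173, and 15 of the 35 splits of the arrays gave a difference as large (exact permutation, one-sided p = 0.429). That difference turned negative, down to -0.0110, when any 1 of the RFA arrays was left out. Control replicates 2 and 3 correlated at 0.978 with each other and at 0.841 and 0.857 with control replicate 4, while control replicate 3 and RFA replicate 1 correlated at 0.983. The first principal component held 53.1% of the variance and the second 23.3%, and control arrays lay at both ends of the first.

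**Figure D3:**
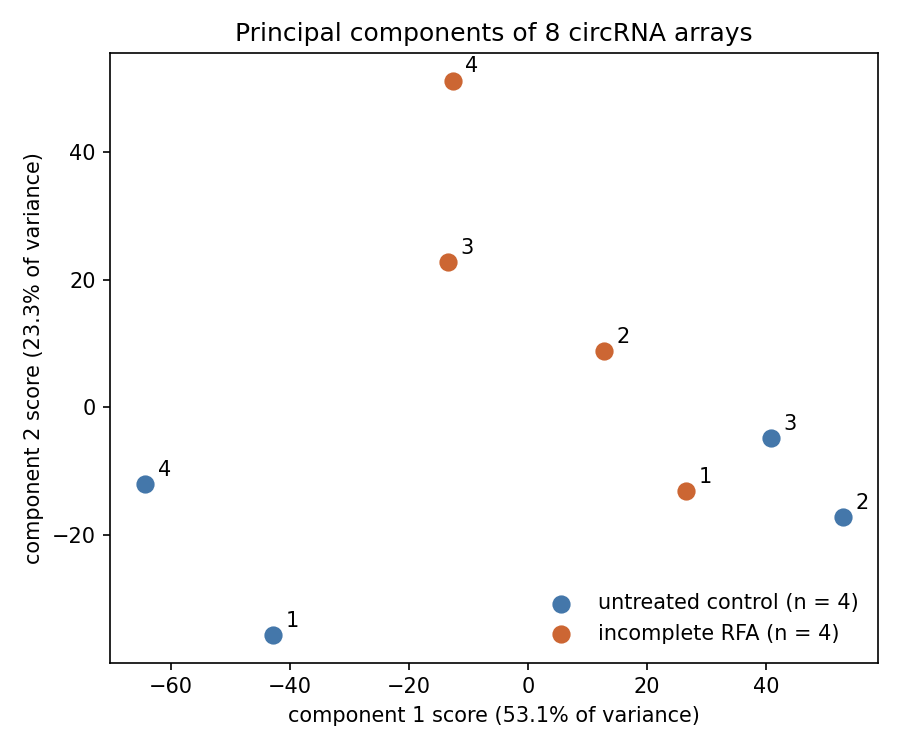
Scores of the 8 arrays on the first (x axis, 53.1% of variance) and second (y axis, 23.3% of variance) principal components of log2 circRNA levels, with 1 numbered point per replicate. Control replicates 1 and 4 lie at -42.8 and -64.2 on the first component and control replicates 2 and 3 at 52.8 and 40.8, with the RFA arrays between them from -13.4 to 26.6.

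The mRNA probes read RNA already digested with RNase R, so their levels need not follow mRNA levels in the tumors. No mRNA passed the threshold among the 47 tested, and the 2 with the smallest p were PRIM1 and RAD54B. PRIM1, the catalytic subunit of DNA primase, was at -3.07 ± 0.62 (SD, n = 4) in control and -1.70 ± 0.73 (SD, n = 4) in RFA tumors on the log2 scale, a log2 fold of 1.36 ± 0.41 (SE) and a limma adjusted p of 0.324. All 4 RFA values of PRIM1 lay above all 4 control values, but it was well above background on only 1 of 4 control arrays against 4 of 4 RFA arrays, and with normexp its log2 fold was 0.21. RAD54B, a helicase-like protein of homologous recombination, was at -3.45 ± 0.77 (SD, n = 4) and -2.43 ± 0.09 (SD, n = 4), a log2 fold of 1.02 ± 0.36 (SE) and an adjusted p of 0.332. It too was well above background on 1 of 4 control arrays and 4 of 4 RFA arrays, and with normexp its log2 fold was 0.097. At an unadjusted p under 0.05, limma gave 4 mRNAs, where 2.35 are given by chance, and with 1 array left out it gave 2 to 7, with array weights 7 and with normexp 2.

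Among the cell cycle genes fixed as a list, 3 mRNAs were tested and 0 passed over all mRNAs. Adjusted over the list alone, 1 of the 3 passed, PRIM1 with an adjusted p of 0.0207. The other members were CENPE, a kinetochore motor, with a log2 fold of 0.40 ± 0.34 (SE), and the cyclin CCNA2 with 0.21 ± 0.26 (SE). Of the DNA repair list, 3 of 4 mRNAs on the array were tested and 0 passed over all mRNAs. RAD54B was the only 1 of the 3 past the threshold adjusted over the list alone, with an adjusted p of 0.0453. Neither list adjustment, that of PRIM1 or that of RAD54B, corrected for the number of lists. The helicase WRN had a log2 fold of 0.24 ± 0.25 (SE), the structural maintenance protein SMC6 had -0.14 ± 0.29 (SE), and BRCA1 was above background on 0 arrays. Leaving out control replicate 2 or RFA replicate 2 ended the call of PRIM1 (limma adjusted p = 0.0711 and 0.0755 over its list), and leaving out any array but control replicate 3 ended that of RAD54B (adjusted p from 0.0692 to 0.137 over its list), which without control replicate 3 passed over all 47 mRNAs (adjusted p = 0.00335). With normexp neither passed over its list (adjusted p = 0.166 and 0.281), and RAD54B did not pass with quantile normalization (adjusted p = 0.0750) or median scaling (adjusted p = 0.0557).

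In the hypoxia and angiogenesis list, 0 of 3 tested mRNAs passed over all mRNAs and 0 adjusted over the list alone. The glycolytic enzyme PGK1 had a log2 fold of 0.29 ± 0.31 (SE), and the collagen crosslinking enzymes LOX and LOXL2 had -0.20 ± 0.43 (SE) and -0.01 ± 0.36 (SE). In the chromatin list, 0 of 2 passed either way. The remodeling subunit BAZ1A had -0.41 ± 0.35 (SE) and the remodeler SMARCAD1 -0.07 ± 0.34 (SE), and the sign of SMARCAD1 flipped when the percentile was taken over probes detected on all arrays, as did that of LOXL2. Without control replicate 4, BAZ1A passed over its list alone (limma adjusted p = 0.0383). The signs of SMC6 and LOX turned with array brightness as a covariate. CPS1, the urea cycle enzyme that stood alone for hepatocyte function, had a log2 fold of 0.81 ± 0.54 (SE), with 0 of 1 passing, and without RFA replicate 4 the fold was 0.24. The other 10 lists, among them heat shock, cell death and the markers of stroma, immune cells and endothelium, had 0 members among the mRNA probes.

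ACTB, the cytoplasmic beta-actin often used as a reference transcript, was at 0.57 ± 0.17 (SD, n = 4) in control and 0.05 ± 0.06 (SD, n = 4) in RFA tumors. Its log2 fold was -0.52 ± 0.22 (SE), with every RFA value below every control value and a limma adjusted p of 0.479. Of the 47 mRNAs, only PRIM1 and ACTB had groups that did not overlap, where chance gives 1.43% of probes per direction. EIF3D, a subunit of a translation initiation factor, had a log2 fold of -1.06 ± 0.40 (SE) and an adjusted p of 0.332. The ribosomal protein RPS18 had -0.64 ± 0.37 (SE), the actin-binding profilin PFN1 -0.99 ± 0.58 (SE), the dynein light chain DYNLL1 -0.55 ± 0.36 (SE) and the histone H3-3A -0.48 ± 0.35 (SE). In the other direction, SPP1, the secreted protein osteopontin, had 0.67 ± 0.34 (SE), ODC1, an enzyme of polyamine synthesis, 0.66 ± 0.35 (SE), and the mitotic regulator PIMREG 0.31 ± 0.25 (SE). The adjusted p of these 7 mRNAs ranged from 0.653 to 0.768. Several of these transcripts, such as ACTB, RPS18 and H3-3A, have pseudogenes or close copies, and mouse transcripts of the host were not told apart from human ones.

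**Figure D4:**
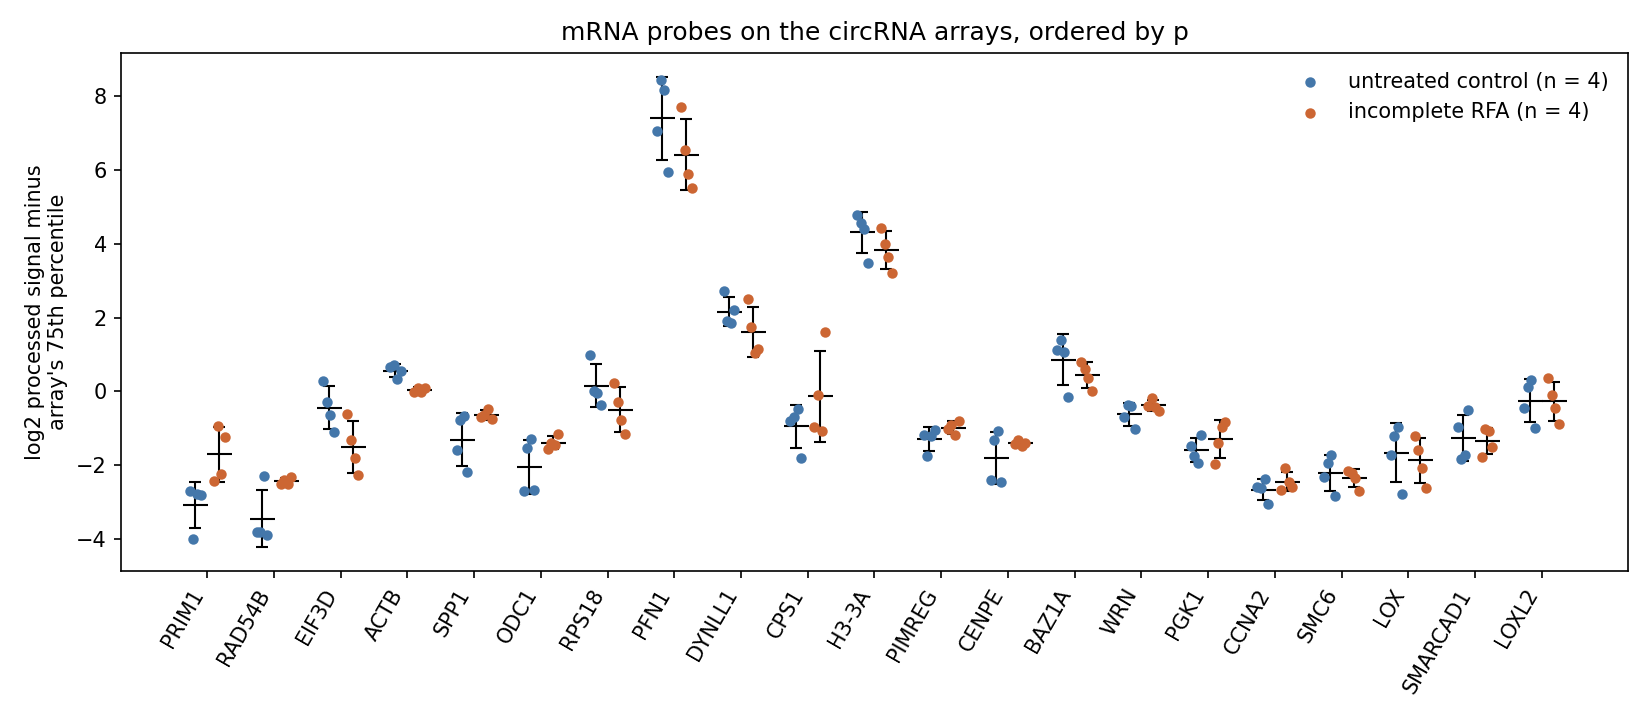
Log2 processed signal minus the array's 75th percentile (y axis) of the named mRNAs, without ACTG1, ZZZ3 and GAPDH, in order of p (x axis). Each array is 1 point, with the group mean as a horizontal mark and the SD as a bar, for 4 control and 4 RFA arrays. PRIM1 lies higher in all 4 RFA arrays and ACTB lower in all 4 than in any control array, and no mRNA passed adjusted p under 0.05 among the 47 tested.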

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

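A single array lay far from the other 3 of its group in 2 of the 94 sets of 4 values examined, where chance gives about 1 in 20, or 4.70. Both are control values of the mRNAs with the smallest p. PRIM1 was at -4.0 on control replicate 2 and between -2.81 and -2.69 on the other control arrays, a gap of 0.903 of the group's range. RAD54B was at -2.29 on control replicate 3 and between -3.89 and -3.80 on the other control arrays, a gap of 0.940 of the range.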

How the results depend on the processing

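The alternatives for the mRNAs, variance ratio and groups that do not overlap, the median signal, cyclic loess, the 2 covariate fits and the deposited table at an unadjusted threshold were chosen after the data were seen. The count of circRNAs past adjusted p under 0.05 stayed at 0, in total and in each direction, in every fit run, from 0 to 0 when each array was left out, and also with a fold of at least 1.5 added. It became 361 (214 higher, 147 lower; 163 to 711 with arrays left out) at an unadjusted p under 0.05 with a fold of at least 1.5, and 131 (67 higher, 64 lower) at that threshold in the deposited log2 table, because the correction for the number of tests was dropped. The number at an unadjusted p under 0.05 was 418, and ranged from 164 to 741 when an array was left out. It was 551 with the percentile over probes detected on all arrays, 240 with normexp, 869 with array brightness and 1257 with the first principal component as a covariate, whose smallest adjusted p was 0.113. The fit with the replicate block gave 0 circRNAs and a smallest adjusted p of 0.191. Same-numbered arrays deviated together with correlations of -0.205, 0.283, -0.391 and 0.381. Of the 8 arrays, 2 correlated best with their own number, but single pairs cannot exclude pairing. The folds of the 20 named circRNAs shrank with normexp, to between 0.11 and 0.81 for the 10 higher (median 0.20 against 0.98 in the main fit) and between -1.88 and -0.07 for the 10 lower (median -0.66 against -1.30), and in the deposited table to medians of 0.37 and -0.86. No slide block was run, as all arrays shared a slide. The host gene list, circRNA list and class results were not run, the set tests among them, because the files do not pair probes with names. How far weak signal limits the circRNA values shows in the negative probes, of which up to 20.7% of spots were marked above background.

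The count of mRNAs past the threshold was 0 in the fits run except 1 without control replicate 3, a range of 0 to 1 with arrays left out. The count of list members past the threshold adjusted over the list alone was 2, and it was 1 with quantile normalization, median scaling, no filter, array weights and cyclic loess, 0 with normexp, with normexp and quantile normalization and with the stricter filter, which tested neither PRIM1 nor RAD54B, and 0 to 2 with arrays left out. Over the alternatives, the list-adjusted p of PRIM1 ranged from 0.00565 to 0.166 and that of RAD54B from 0.000214 to 0.338. Leaving out 1 array moved the log2 fold of 19 of the 24 named mRNAs by more than 1.5 times. The sign of a named mRNA's log2 fold turned as follows, with no call in any of these cases. With array brightness as a covariate SMC6 became 0.015, LOX 0.12, LOXL2 0.25 and ACTG1 0.00501. With the percentile over probes detected on all arrays, SMARCAD1 became 0.00011 and LOXL2 0.061, and with array weights SMARCAD1 became 0.33 and GAPDH -0.049. With arrays left out, SMC6 ranged from -0.35 to 0.015, LOX from -0.57 to 0.043, SMARCAD1 from -0.27 to 0.18, LOXL2 from -0.26 to 0.20 and GAPDH from -0.11 to 0.30. The group difference in the log2 percentile, -0.02, ranged from -0.12 to 0.10 with arrays left out, that in detected circRNAs, 105.8, from -233 to 404, and the difference in array similarity from -0.0110 to 0.0165. Apart from the causes named, the cause was not tested.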

Other observations

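The tests of the mRNAs, of the array axis, of the other splits of the arrays and of the spread were written after the values were seen, while the count of circRNAs in the real grouping was planned. PFN1 had an SD of 1.13 among control and 0.96 among RFA arrays on the log2 scale, and ACTG1, the gamma-actin, had 1.44 and 0.99. ZZZ3, a subunit of a histone acetyltransferase complex, had 0.94 and 1.17, and its log2 fold was -0.58 ± 0.59 (SE), which became -0.019 without RFA replicate 4. GAPDH, a glycolytic enzyme used as a reference, had 0.51 and 0.31 and a log2 fold of 0.10 ± 0.31 (SE), a sign that flipped with array weights. ACTB had 0.17 and 0.06, so the 2 actins differed in how much they varied. ACTG1 had a log2 fold of -0.55 ± 0.67 (SE), a sign that flipped with array brightness as a covariate. Over the 47 mRNAs, the median SD was 0.57 among control arrays and 0.31 among RFA arrays. The other 23 mRNA probes did not reach the detection rule. Above background on 0 arrays were the repair genes BRCA1 and EXO1, the chloride channel CFTR, the T cell factor TCF7, the activation marker CD69 and the respiratory chain subunit COX4I1.

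The main axis of the circRNA arrays crossed the groups, with control arrays at both ends. A trend with signal level was argued against as its cause, since the axis held 53.4% of the variance after cyclic loess and 53.1% before. Brightness of the hybridization could contribute, since the scores correlated with the orientation spots over the 8 arrays (r = 0.784, exact permutation p = 0.0267, adjusted 0.0401 over 3 relations; rho = 0.738, exact p = 0.0458, adjusted 0.0688), with r = 0.721 without control replicate 3 and RFA replicate 1, and with values centred within each group (r = 0.843, exact permutation p = 0.00521, adjusted 0.0156; rho = 0.833, exact p = 0.0104, adjusted 0.0312), with r = 0.927 without the same 2. Linear RNA left after the digestion may also contribute, if the mRNA probes measure it, and was not told apart from brightness. The scores correlated with the mean mRNA level (r = 0.877, exact permutation p = 0.00563, adjusted 0.0169, and rho = 0.738, exact p = 0.0458, adjusted 0.0688). Without control replicate 4 and RFA replicate 4, r was 0.811. Centred within groups, they also correlated (r = 0.876, exact permutation p = 0.0104, adjusted 0.0156, and rho = 0.833, exact p = 0.0278, adjusted 0.0417), with r = 0.815 without the same 2. The mRNAs did not all move together, since 26 of the 47 correlated with the scores above 0.5 and 4 below -0.5. The third relation, to the number of detected circRNAs, had r = -0.328 (exact p = 0.423, adjusted 0.423) and rho = -0.50 (exact p = 0.216, adjusted 0.216), with r = -0.428 without control replicate 1 and RFA replicate 2, and centred within groups r = -0.338 (exact p = 0.378, adjusted 0.378) and rho = -0.50 (exact p = 0.177, adjusted 0.177), with r = -0.429 without the same 2; composition of the tumors was not tested.

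The counts past the threshold cannot be set against other groupings. The real grouping gave 0 circRNAs, in total and in each direction, and 0 mRNAs, so all 35 splits of the 8 arrays necessarily gave at least as many, and this says nothing about chance. The highest of the others were 1838 circRNAs, 991 in 1 direction, and 5 mRNAs. The split with 1838 joins control replicates 1 and 4 with RFA replicates 3 and 4, the 4 arrays with negative scores on the first component. It points to the same structure of the samples or arrays as the main axis and is not separate evidence. These 4 had mean mRNA deviations from -0.39 to -0.05 and the other 4 from 0.14 to 0.21. Orientation spot brightness on the log2 scale ran from 15.29 to 15.94 in the 4 joined arrays and from 15.93 to 17.06 in the other 4. Linear RNA left after the digestion stays open as the source of this structure, as does brightness, and the 2 were not told apart. At an unadjusted p under 0.05, 11 of the 35 splits gave at least the 418 circRNAs of the real grouping, with 3290 the highest of the others, so chance was not excluded there.

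Control arrays were spread wider than RFA arrays. The median SD over circRNAs was 0.51 among control and 0.31 among RFA arrays, 74.4% of circRNAs had the larger variance in control, and the median ratio of variances was 2.70, or 1.43 on the log2 scale. Of the 35 splits, 2 gave a ratio as far from 1, the other at 1.81 on the log2 scale, so chance was not excluded. The ratio ranged from 2.21 to 3.78 when an array was left out, with an exact permutation p from 0.0286, the smallest that design can give, to 0.286. Position on the slide may set the spread as well as treatment may, and they cannot be told apart, since 0 slide rows held both groups.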
